A study of Arabidopsis thaliana with 7 samples.

How the data were processed

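Small RNAs of Arabidopsis thaliana were measured by Illumina sequencing of 7 libraries. The RNA sequenced was total small RNA, RNA bound by an anti-FLAG gel from plants that carry FLAG-tagged AGO3 (IP), and RNA bound by the same gel from wild-type plants (mock IP). Siliques gave 3 libraries and plantlets gave 4. Each group held 1 library.

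The deposited tables list, for each library, a sequence and its counts, with no header and no normalization, as the values themselves show. The submitters' processing notes name CASAVA 1.8 and 1.8.2 and the genome build TAIR10 without saying what each was used for. The aligner, the mismatches allowed and the adapter trimming are not given in the sources used here. Sequences were 15 to 44 nt long in siliques and 15 to 35 nt in plantlets.

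The listed sequences read along the plus strand of the reference. Many sequences were listed in both orientations, and 97.7 to 99.7% of those had equal counts in both. Each such pair was therefore counted once, with the larger count. The strand of a read, and with it the base at its 5′ end, is not recorded in such a table. The planned share of reads that begin with A was replaced by the share of reads with A at the first position in either orientation. This share is an upper limit of the 5′ A share. The share with A in both orientations, which is a lower limit, and the share at inner positions of the same reads were computed beside it. Reads at MIR genes were taken as sense.

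Sequences of 18 to 30 nt were matched without mismatches to the TAIR10.1 assembly, chloroplast and mitochondrion included, with Python 3.11.15 and NumPy 2.4.6. A read that matched several positions was divided equally among them. Of the reads of 18 to 30 nt, 86.9 to 91.9% matched, and these reads per library were the denominator of every share and of RPM (counts scaled to the matched reads of a library). Reads of 20 to 25 nt were summed over 38321 annotated features. Transposon genes carry the type pseudogene in this annotation. The 25S rRNA was taken as the 4000 nt downstream of each nuclear 5.8S gene. The 5S arrays and the centromere repeats are unannotated and fell among the unannotated reads. Reads whose 5′ end lay within 2 nt of that of an annotated mature miRNA (428 entries) were counted for it.

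For each of the 6 comparisons, a feature was measured with at least 100 reads in both libraries together, and its RPM ratio was called higher or lower at 2-fold. Ratios have exact conditional binomial 95% intervals and shares have exact Clopper-Pearson 95% intervals (SciPy 1.17.1, pandas 2.3.3). A count of 0 was set to a floor of 3 counts, which is 0.0719 to 0.253 RPM over the libraries. No test across conditions could be made with 1 library per group, and no p-value is given. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

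The features to be named were fixed before the data were examined. They were, per comparison, the 5 highest and the 5 lowest ratios past 2-fold with an interval clear of 1, the 5 features with the most reads in the first library among those at least 2-fold higher, the 4 members with the most reads of each of 9 fixed lists, and AGO3 and AGO2. The lists held development, nutrient, young and pollen miRNAs, TAS loci, protein-coding genes with secondary siRNAs, imprinted genes, methylation feedback genes and Argonaute genes. FWA and SDC are in both the imprinted and the methylation feedback list. For each list the median log2 ratio and its percentile among 10000 random lists of equal size, drawn for each member from the 200 features nearest in abundance, were computed. A percentile describes these libraries and is no test. Random members were drawn independently, whereas members of a list can share reads that match several positions and are then not separate measurements. The median log2 ratio of all features was subtracted where a change is given relative to all features, and such a value does not depend on the scaling of the libraries. Mature miRNAs, chromosome windows of 100 kb with more pseudogene than protein-coding bases, and lists of photosynthesis and proteasome genes were chosen after the data were seen.

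Alternatives were reads with 1 match, a denominator without structural and organellar RNA, TMM scaling (edgeR 4.0.16, R 4.3.3), minimums of 20 and 1000 reads, distinct sequences, reads of 24 nt alone, reads of 20 to 25 nt, removal of the 10 most abundant sequences of each library and, added later, the sum over both listed orientations. The matching and the ratios were tested on simulated data. Among 2998 simulated sequences no genome position had a wrong sum. With 200 of 4382 features changed 4-fold in Poisson counts, 100% of these and 0 others passed 2-fold with an interval clear of 1. Of the intervals, 96.28% held the true ratio. Variation between libraries beyond counting error and a shift in composition were not simulated. Figures were drawn with matplotlib 3.10.9. Reads of 15 to 17 nt, reads over 30 nt and reads without an exact match were left out of the comparisons.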

Results

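Small RNAs of Arabidopsis thaliana (Col-0) were read from 7 libraries, 1 per group, to find which of them AGO3, an Argonaute protein, holds. In siliques collected 1 to 5 days after pollination from plants on soil, the groups were total small RNA of the wild type, an immunoprecipitation (IP) of FLAG-tagged AGO3, and a mock IP in which wild-type tissue met the same anti-FLAG gel. In plantlets on plates under continuous light, the groups were total small RNA and the AGO3 IP, each untreated and after syringolin A (SylA), a proteasome inhibitor made by Pseudomonas syringae. The labels give no dose or duration of SylA, and no mock IP of plantlets was among the libraries. For total RNA of plantlets the labels give Col-0 as the source and the tagged line as the genotype, so its genotype is open.

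Reads of 18 to 30 nt that matched the genome numbered 25995042 in the mock IP, 36497525 in the AGO3 IP and 41720161 in total RNA of siliques. Untreated plantlets had 13509065 such reads in total RNA and 16951089 in the AGO3 IP, and SylA plantlets had 11859042 and 17871289. A count of 0 allows up to 0.0719 RPM (counts scaled to the matched reads of a library) in total silique RNA and up to 0.253 in SylA total RNA, the libraries with the most and the fewest reads. With no replicates, no difference could be set against a spread between samples, and the intervals given are 95% intervals of counting error alone. Percentiles of lists describe these libraries only, and members of a list can share reads that match several positions. Changes given relative to all features have the median log2 ratio of the comparison subtracted and are the same under every scaling of the libraries.

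Reads of 24 nt made up 39.6% of the mock IP, 36.2% of the AGO3 IP and 29.5% of total RNA in siliques. In plantlets the share of 24-nt reads was 13.2% of total RNA and 22.5% of the AGO3 IP, and after SylA it was 18.01% of total RNA and 74.8% of the AGO3 IP. The widest interval of these shares was 17.99 to 18.03%, in SylA total RNA. The 21-nt share of the plantlet AGO3 IP was 46.4% untreated and 5.93% after SylA. Because the strand of a read is not recorded, the base at its 5′ end was read in both orientations. A stood at the first position in either orientation in 98.1% of 24-nt reads of the SylA IP, 87.0% of the untreated plantlet IP and 85.5% of the silique IP. This share was 76.1% in the mock IP, 71.1% in total silique RNA, 62.8% in untreated and 67.0% in SylA total plantlet RNA. At inner positions of the same reads it lay between 46.4 and 49.4%. The share with A in both orientations, a lower limit for 5′ A, ran from 18.1 to 31.8%.

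**Figure D1:**
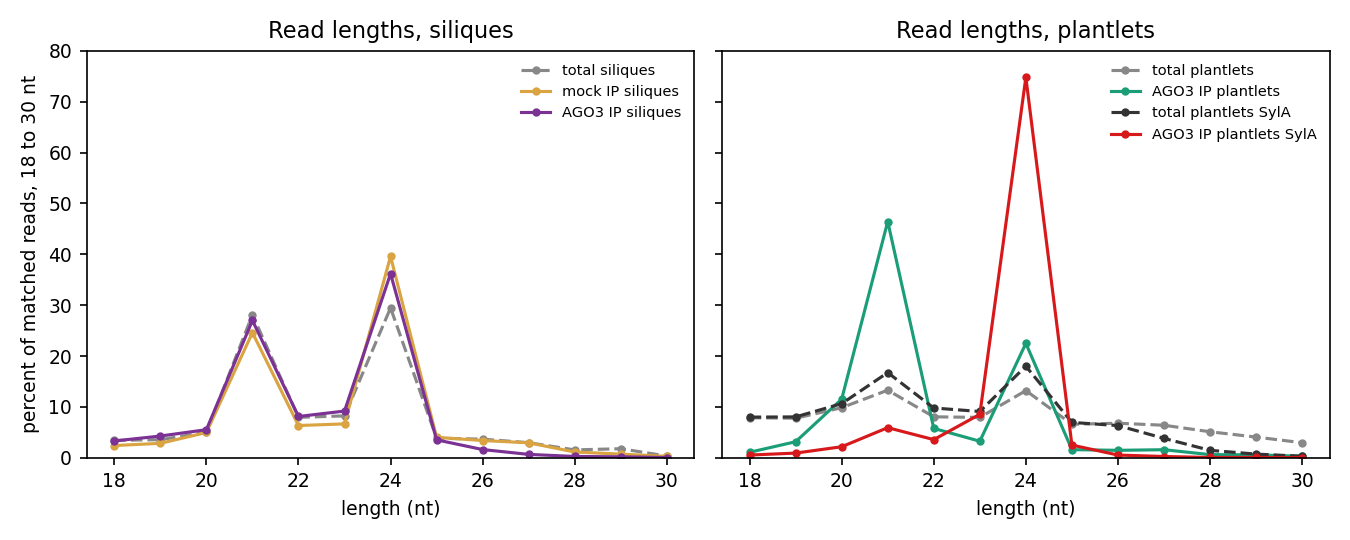
Share of matched reads (percent, vertical axis) by read length (nt, horizontal axis) for the silique libraries (left) and the plantlet libraries (right), 1 line per library. The SylA AGO3 IP peaked at 24 nt with 74.8% of its reads, and the untreated plantlet AGO3 IP at 21 nt with 46.4%.

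Reads at MIR genes made up 54.8% of the untreated plantlet AGO3 IP, 9.50% of untreated total plantlet RNA, 6.46% of the SylA AGO3 IP and 13.5% of SylA total RNA. In siliques the miRNA share was 19.8% of the AGO3 IP, 20.1% of the mock IP and 22.8% of total RNA. Pseudogene reads, which in this annotation hold the transposon genes, made up 25.04% of the SylA IP and 2.13 to 6.14% of the other libraries. Unannotated reads made up 50.1% of the SylA IP and 18.9% of the untreated plantlet IP. Structural and organellar RNA took 72.7% of untreated total plantlet RNA, 62.7% of SylA total RNA, 14.99% of the untreated IP and 6.57% of the SylA IP. This difference enters every ratio of a plantlet IP to total RNA.

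**Figure D2:**
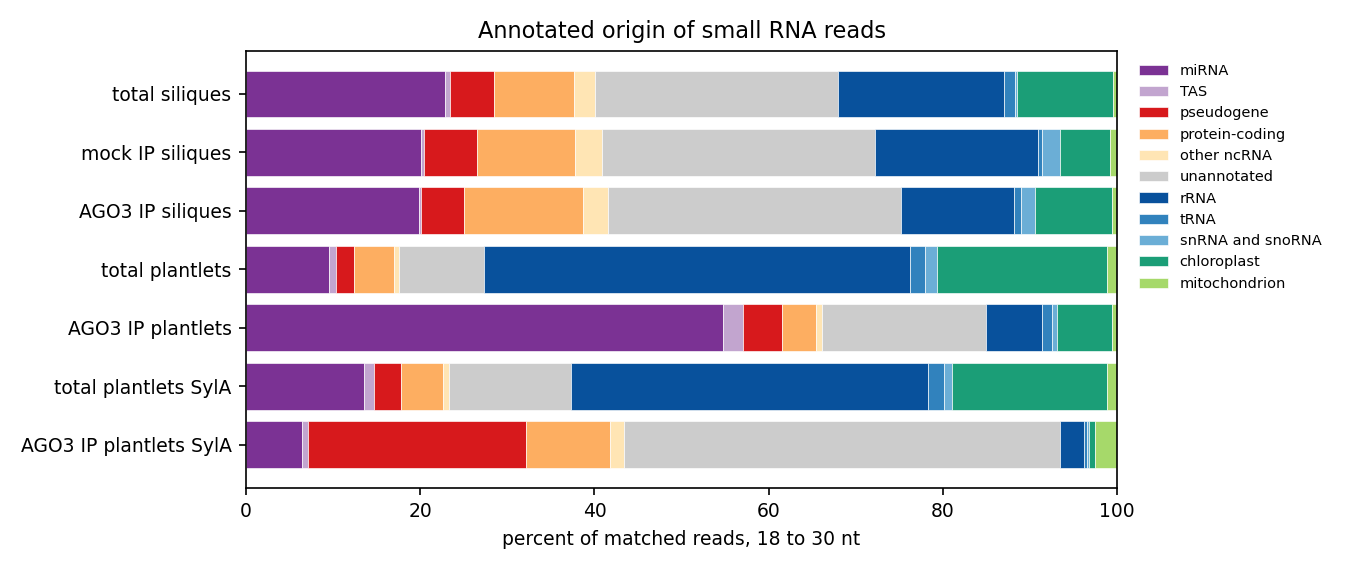
Share of matched reads of 18 to 30 nt (percent, horizontal axis) by annotated origin, 1 bar per library. The miRNA part is 54.8% of the untreated plantlet AGO3 IP and 6.46% of the SylA AGO3 IP, and the pseudogene part is 4.57% and 25.04%.

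The AGO3 IP of siliques was set against the mock IP to find what the tagged protein holds beyond the gel. The 24-nt share differed by -3.38 points, and the share of 24-nt reads with A in either orientation by 9.38 points. The AGO3 locus itself (AT1G31290, chromosome 1, 11188120 to 11192585, TAIR10.1) rose from 11.8 RPM (10.6 to 13.2) in the mock IP to 120.3 RPM (117 to 124), a ratio of 10.1 (9.04 to 11.4). Of 4520 reads that matched this locus in the silique IP, 4519 lay in exons, which cover 90.1% of it, and 50.9% of its reads were 21 nt long. The genotype label of the tagged line names an ago3 allele and an AGO3 transgene. Since the mock IP and total RNA of siliques are of the wild type, genotype and tagged protein differ together. At this locus, reads of a transgene cannot be told apart from reads of the gene. AGO2 (AT1G31280) had a ratio of 1.24, but 71.3 to 98.2% of the reads that match AGO2 in the 7 libraries also match MIR403, whose miRNA targets AGO2, so its own reads are not set apart. Of 7570 features with at least 100 reads, 795 were at least 2-fold higher in the AGO3 IP, 1209 were at least 2-fold lower and 73.5% lay within 2-fold, at a median log2 ratio of -0.28. TMM scaling moved every log2 ratio by 0.27 and gave 1048 higher and 811 lower features, and a denominator without structural and organellar RNA gave 743 and 1334.

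The highest ratio to the mock IP was that of the ncRNA gene AT2G00840 (chromosome 2, 11812662 to 11813078), with 2929 reads against 1, a ratio of 2086 (374 to 82426.5). AT1G59722, AT3G30730 and LAC7 (AT3G09220, a laccase gene) followed with ratios of 228, 145 and 119 on 1 or 2 mock reads, for which the lower bounds were 62.9, 25.8 and 32.8. AT5G42410 had 584 reads against 0 and was at least 139-fold higher, with 0 taken as the floor of 3 counts. The lowest ratios were those of AT1G06147, AT5G40020, ASN1 (AT3G47340, an asparagine synthetase gene), LCR72 (AT2G02140) and AT3G45940, each with 1 or 2 reads in the AGO3 IP and 179 to 401 in the mock IP. AT3G15960 (ratio 5.91), MIR159a (3.42) and TPS2 (AT1G16980, a trehalose-phosphate synthase gene, 10.04) had the most reads among higher features next to both copies of chloroplast rrn16S (2.10), whose reads have no single match. By class, tRNA features lay 1.195 above all features (97 of 217 at least 2-fold higher), chloroplast features 1.10 above (44 of 116) and snRNA and snoRNA features 0.57 above (77 of 270). Among the fixed lists, the secondary siRNA protein genes had a median 0.78 above all features (percentile 99.96 among 10000 random lists) with 0 of 16 at least 2-fold higher, AT1G62910, AT1G63150, AT1G63080 and RPF3 with ratios of 1.28 to 1.59. TAS loci lay 0.70 above, TAS1C, TAS2, TAS3 and TAS1B with ratios of 0.917 to 1.34, TAS3 passing above 1 under TMM scaling. Development miRNAs lay 0.68 above all features, with MIR159, which targets MYB genes, at 1.94, MIR396 at 1.47, MIR166 at 0.962 and MIR165 at 0.847, the last 2 passing above 1 under TMM scaling. Of 7 imprinted genes, YUC10, of auxin synthesis (4.01), and HDG8 (16.5) were higher and AGL36 (0.984, above 1 under TMM scaling) and HDG9 (0.769) were not. Nutrient miRNAs lay 0.46 above all features with MIR398, MIR408, MIR397 and MIR399 at ratios of 0.371 to 1.64 (MIR398 above 1 under TMM scaling only), and young miRNAs lay at -0.04 with MIR158, MIR161, MIR163 and MIR869 at 0.699 to 1.47. Methylation feedback genes lay at -0.04, with AT4G08680, SDC, FWA and DML1 at 0.590 to 0.925, AT4G08680 and FWA passing above 1 under TMM scaling. Argonaute genes (5 measured) lay at -0.71, with AGO1 at 0.504 and AGO9 at 0.0140 (6 reads against 306), and the pollen miRNA MIR845 had a ratio of 0.523. AGO9 had 11.8 RPM in the mock IP, 0.844 in total RNA and 0.167 in the AGO3 IP, so the mock IP also stood above total RNA.

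**Figure D3:**
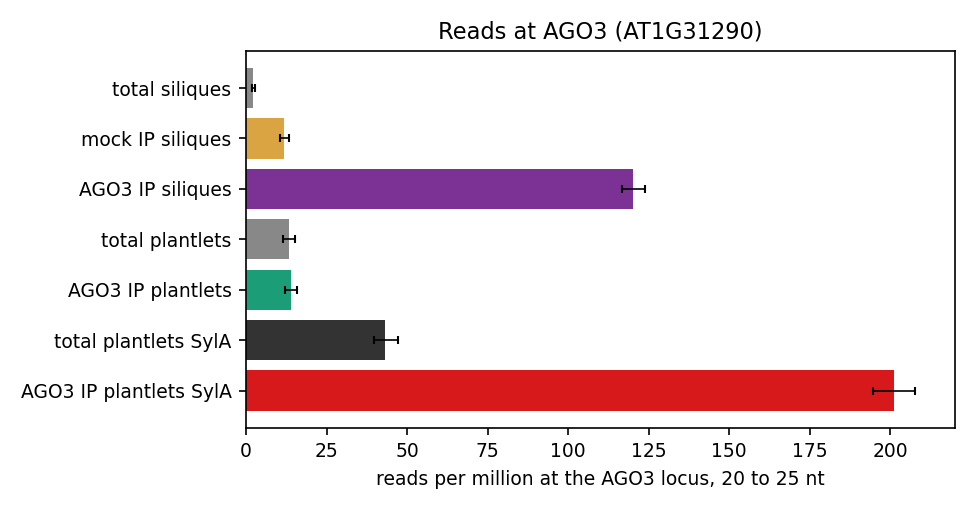
Reads of 20 to 25 nt at the AGO3 locus (RPM, horizontal axis) in each library, 1 bar per library with 95% Poisson intervals of counting error. The silique AGO3 IP (120.3) and the SylA AGO3 IP (201) stand above the other libraries, which lie between 2.15 and 43.3, although the SylA IP falls under SylA total RNA with TMM scaling.

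Mature miRNAs were grouped by their annotated first base after the data were seen. Against the mock IP, those that begin with A lay 1.51 above all features on the log2 scale and those that begin with U lay 0.47 above. Those with G lay 1.14 above (2 of 5 at least 2-fold higher) and those with C 0.02 above, so the excess was not particular to A. Of 8 with A, 5 were at least 2-fold higher, namely miR393-3p (8.79), miR390-5p (2.93), miR398-5p (2.81), miR408-5p (2.49) and miR840-5p (2.20). Of 58 that begin with U, 6 were higher and 3 lower.

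Against total RNA of siliques, the AGO3 IP was compared to find which small RNAs of the tissue were held in excess. The 24-nt share was 6.73 points above total RNA and the share with A in either orientation 14.4 points above. AGO3 had 120.3 RPM against 2.15 (1.73 to 2.65), a ratio of 55.7 (45.2 to 69.5), and AGO2 had a ratio of 0.789. Features of snRNA and snoRNA had the highest class median, with 221 of 267 at least 2-fold higher and a median 2.96 above all features. This class made up 1.61% of the AGO3 IP and 0.254% of total RNA, but also 2.06% of the mock IP. The highest ratios were those of AT1G72645 (chromosome 1, 27348261 to 27349219) at 672 (326 to 1672), the snoRNA genes AT5G02315 at 312, AT2G05765 at 217 and AT2G35742 at 112, and AT5G42410 at 223 on 3 reads in total RNA (75.8 to 1082). The lowest were AT1G06147, AT5G07575, AT5G40020, AT3G23633 and AT3G09960, with 1 to 4 reads in the IP and 322 to 966 in total RNA. Among higher features, chloroplast rrn16S (both copies, 4.41), chloroplast trnS (97.7), AT3G15960 (4.51) and TPS2 (6.78) had the most reads. Of 7935 features, 939 were higher, 806 lower and 78.0% within 2-fold, at a median of -0.19. TMM scaling moved log2 ratios by 0.17 and gave 1118 higher and 569 lower features, and the denominator without structural and organellar RNA moved them by -0.15 and gave 829 and 1091.

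The miRNA, TAS and secondary siRNA lists lay under all features in this comparison. Development miRNAs lay at -0.52 (8 of 20 at least 2-fold lower, 6 under TMM scaling), young miRNAs at -0.87, TAS loci at -0.90 and secondary siRNA protein genes at -0.75, at percentiles of 0 to 0.05 among random lists. MIR166, MIR165, MIR159 and MIR396 had ratios of 0.822 to 0.982, MIR166 and MIR396 passing above 1 under TMM scaling, and MIR158, MIR161, MIR163 and MIR447 had ratios of 0.353 to 0.776. TAS1C, TAS2, TAS3 and TAS1B had ratios of 0.432 to 0.739, and AT1G63080, AT1G62910, AT1G63150 and AT1G63130 had ratios of 0.450 to 0.747. Nutrient miRNAs lay at -0.27, with MIR398, MIR408 and MIR397 at 0.634 to 1.05 (MIR408 under 1 without structural and organellar RNA in the denominator) and MIR399 at 0.0804, and the pollen miRNA MIR845 at 0.313. YUC10 (3.91), HDG8 (7.83) and AGL36 (1.44) were above total RNA, MYB3R2 was at 0.730, and the imprinted genes as a list lay 0.04 from all features. Methylation feedback genes lay 0.05 from all features, with AT4G08680, SDC, FWA and AT5G17125 at 0.661 to 0.958, AT4G08680 and AT5G17125 passing above 1 under TMM scaling. Argonaute genes (3 measured) lay at -0.05, with AGO1 at 0.847. Mature miRNAs that begin with A lay at -0.61 and those with U at -0.48 relative to all features.

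In untreated plantlets the AGO3 IP was compared with total RNA, since no mock IP was among the libraries. The 24-nt share was 9.28 points above total RNA, but it was -3.35 points from it without structural and organellar reads. The share of 24-nt reads with A in either orientation was 24.2 points higher. AGO3 had 13.9 RPM (12.2 to 15.8) against 13.2 (11.3 to 15.3), a ratio of 1.06 (0.866 to 1.29) that fell under 1 under both other scalings, and relative to all features it lay at -1.03. AGO2 had a ratio of 2.69, which fell under 1 without structural and organellar RNA in the denominator. Of 4982 features, 2927 were higher and 802 lower, 25.2% lay within 2-fold and the median log2 ratio was 1.11. TMM scaling moved log2 ratios by -1.10 and gave 158 higher and 941 lower features, and the denominator without structural and organellar RNA moved them by -1.64 and gave 39 and 1205.

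MIR401 (AT4G08116, chromosome 4, 5020237 to 5020486) had the highest ratio of this comparison at 42.4 (31.1 to 59.2). The tRNA gene AT2G24380 (13.2), AT3G54680 (12.1), AT4G03380 (11.9) and a mitochondrial ncRNA at 92783 to 92818 (10.2) followed. The lowest were AtCDC48B (AT3G53230), the snoRNA gene AT1G75166 and PAD2 (AT5G66140, a proteasome subunit gene), with 1 read in the IP and 117.5 to 163.5 in total RNA, and AT2G20720 and PA200 (AT3G13330, a proteasome activator gene), with 0 reads against 389 and 376 and ratios of at most 0.00615 and 0.00636 at the floor of 3 counts. MIR158a (4.46) and MIR166a to MIR166d (7.01 to 7.27) had the most reads among higher features. Reads that match several MIR166 genes were divided equally among them, so these genes are not separate results. Relative to all features, development miRNAs lay 0.69 above (18 of 19 at least 2-fold higher, 8 under TMM scaling and 3 without structural and organellar RNA in the denominator, percentile 99.81), young miRNAs 0.60 above, TAS loci 0.56 above and secondary siRNA protein genes 0.38 above. MIR166, MIR165, MIR396 and MIR159 had ratios of 2.88 to 8.33, and MIR158, MIR161, MIR841 and MIR173 had ratios of 1.39 to 5.02. TAS1C, TAS2, TAS3 and AT3G25795 had ratios of 2.46 to 3.62, AT1G63130, AT1G62910, AT1G63080 and AT1G63150 of 2.71 to 3.17. Nutrient miRNAs lay 0.25 above all features with MIR398, MIR408, MIR399 and MIR827 at 1.72 to 3.89. Imprinted genes lay 0.30 above with AGL36, MYB3R2, FWA and SDC at 1.51 to 2.90, and methylation feedback genes 0.23 above with AT4G08680 at 2.23 and AT5G17125 at 3.90. Argonaute genes (3 measured) lay at -0.04 with AGO1 at 2.11. Of these members, MIR159, MIR161, MIR399, MIR827, TAS1C, AT1G63130, AT1G62910, AT1G63150, AGL36, MYB3R2, FWA, SDC, AT4G08680 and AGO1 fell under total RNA without structural and organellar RNA in the denominator. Ribosomal RNA (-4.12), tRNA (-3.89), chloroplast (-3.48) and snRNA and snoRNA features (-3.30) lay under all features and under total RNA with each scaling. Annotated mature miRNAs with A as first base lay 0.30 above all features and those with U 0.78 above, so those with U lay higher here.

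After SylA the AGO3 IP was compared with SylA total RNA. The 24-nt share was 56.8 points above total RNA, and the share of 24-nt reads with A in either orientation was 31.1 points above it. AGO3 had 201 RPM (195 to 208) against 43.3 (39.6 to 47.2), a ratio of 4.65 (4.24 to 5.11) that fell under 1 under TMM scaling, at -0.31 relative to all features. AGO2 had a ratio of 0.514. Of 6961 features, 5859 were higher and 829 lower, 3.92% lay within 2-fold and the median log2 ratio was 2.53. TMM scaling moved log2 ratios by -2.49 and gave 984 higher and 1354 lower features, and the denominator without structural and organellar RNA moved them by -1.32 and gave 4050 and 981. Pseudogene features lay 0.45 above all features and 3620 of 3644 were at least 2-fold higher, against 823 under TMM scaling. The pseudogene AT2G07812 (chromosome 2, 3249077 to 3249394) had the highest ratio, 147 (26.2 to 5845) on 1 read in total RNA, followed by mitochondrial ncRNAs at 92499 to 92522 (57.3), 86560 to 86583 (51.8) and 81633 to 81649 (45.5) and the lncRNA gene AT3G06065 (38.8 on 2 reads, 10.5 to 324). MIR8175 (AT2G05455) was lowest at 0.00338, next to chloroplast ArthCt100 (3 reads against 480), trnQ (0.00436) and both copies of trnL (0.00494). Most reads among higher features fell to AT2G08986 (10.001), AT1G40104 (7.37), AT2G06555 (7.36), AT3G41762 (6.33) and AT3G43730 (8.65).

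The lists of miRNAs, TAS loci and secondary siRNA genes lay under all features in the SylA IP. Development miRNAs lay at -3.66, nutrient miRNAs at -4.09, young miRNAs at -3.64, TAS loci at -3.71, secondary siRNA protein genes at -3.54 and Argonaute genes at -3.49. The Argonaute median rests on 3 genes and is that of AGO2, most of whose reads also match MIR403 (79.1% in the SylA IP). AGO3, in the same list, had 201 RPM in the IP against 43.3 in total RNA. MIR166, MIR165, MIR157 and MIR396 had ratios of 0.369 to 0.683, TAS1C, TAS2, TAS3 and TAS1A of 0.363 to 0.617, and AT1G62910, AT1G63130, AT1G63080 and AT1G63150 of 0.440 to 0.561. MIR398, MIR399 and MIR827 had ratios of 0.234 to 0.340 and MIR408 of 1.25. MIR158, MIR161 and MIR163 had ratios of 0.276 to 0.421 and MIR840 of 4.14, and AGO1 of 0.474, MIR408 and MIR840 falling under 1 under TMM scaling. Imprinted genes (7 of 7) and methylation feedback genes (5 of 5) were at least 2-fold higher. Both medians, however, lay at -0.42 relative to all features and fell under 0 under TMM scaling. Both lists hold FWA and SDC, so the lists are not separate results. AGL36, MYB3R2, FWA and YUC10 had ratios of 3.72 to 7.67, AT4G08680 of 11.4, AT5G17125 of 12.3 and IBM1 of 3.03, and MYB3R2, FWA and IBM1 fell under 1 under TMM scaling. Mature miRNAs that begin with A lay at -2.60 and those with U at -4.23 relative to all features. The A-starting miR840-5p (4.22), miR408-5p (3.97) and miR390-5p (2.32), named after the values were seen, were higher than in total RNA but not under TMM scaling, 4 of the 11 that begin with A were at least 2-fold lower, and so were 54 of 61 that begin with U.

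**Figure D4:**
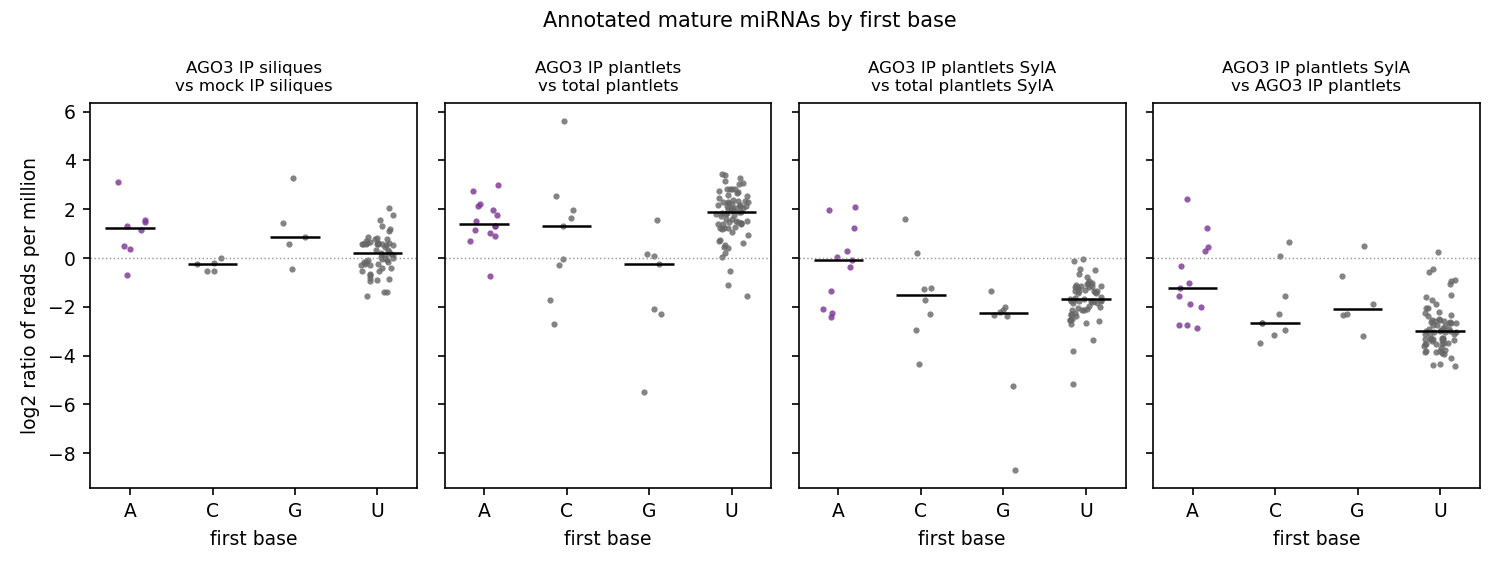
Log2 ratio of RPM (vertical axis) of each annotated mature miRNA by its first base (horizontal axis) in 4 comparisons, 1 point per miRNA, with a line at the median. In the silique IP against the mock IP the median of those with A is 1.23 and of those with U is 0.19, and in the SylA IP against the untreated IP they are -1.23 and -3.00. For the untreated plantlet IP against total RNA these medians are 1.41 and 1.89. The level of each panel moves with the scaling, and the distance between bases does not.

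The SylA IP was set against the untreated IP to see what AGO3 held after the treatment. The 24-nt share rose by 52.3 points, by 32.5 points without the 10 most abundant sequences of each library, and by 0.625 points among distinct sequences. The 10 most abundant sequences held 50.9% of the untreated IP and 5.66% of the SylA IP. AGO3 rose from 13.9 to 201 RPM, a ratio of 14.4 (12.7 to 16.5), and AGO2 had a ratio of 0.315. Pseudogene features lay 0.34 above all features, with 3593 of 3716 at least 2-fold higher and 873 under TMM scaling. Of 24-nt reads with 1 match, 42.2% of the SylA IP and 27.3% of the untreated IP fell in the 180 of 1193 windows of 100 kb richer in pseudogene than in protein-coding bases, a measure chosen after the data were seen. Total RNA had 30.9% of such reads there when untreated and 28.1% after SylA. With reads divided among all their matches, the share was 48.5% in the SylA IP and 34.1% in the untreated IP. Total RNA then had 47.5% after SylA and 53.8% when untreated, so the SylA IP lay near or under it. Of 6753 features, 5682 were higher and 398 lower, 9.97% lay within 2-fold and the median was 1.97. TMM scaling moved log2 ratios by -1.95 and gave 1133 higher and 1008 lower features, and the denominator without structural and organellar RNA moved them by -0.14.

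The highest ratios of the SylA IP to the untreated IP were those of the pseudogenes AT4G06557 at 142 (25.1 to 5657), AT2G07809 at 116, AT4G06541 at 114 and AT2G07812 at 105, with 1 to 2.5 reads in the untreated IP, and of NBR1 (AT4G24690, an autophagy receptor gene, chromosome 4, 12741032 to 12744670) at 75.7 (36.5 to 189) with 559 reads against 7. AT2G08986, AT1G40104, AT2G06555, AT3G41762 and AT3G43730 had the most reads among higher features, with ratios of 5.26 to 5.97. The lowest were both copies of chloroplast trnA (0.0254) and trnR (0.0329) and the snoRNA gene AT1G04517 (0.0330). Relative to all features, development miRNAs lay at -4.76 (14 of 19 at least 2-fold lower, 19 under TMM scaling), nutrient miRNAs at -4.30, young miRNAs at -3.87, TAS loci at -4.40, secondary siRNA protein genes at -3.57 and Argonaute genes at -3.23. Only 3 Argonaute genes were measured in this comparison. MIR166 had a ratio of 0.0887, MIR165 of 0.0701, MIR396 of 0.0867, MIR156 of 0.165 and MIR158 of 0.134. MIR161, MIR841 and MIR173 had ratios of 0.149 to 0.343, MIR398, MIR399 and MIR827 of 0.108 to 0.117, and MIR408 of 0.640. TAS1C, TAS2, TAS3 and AT3G25795 had ratios of 0.123 to 0.391, AT1G63130, AT1G63080, AT1G62910 and AT1G63150 of 0.312 to 0.337, and AGO1 of 0.416. AT4G08680 (6.53), AT5G17125 (5.78), AGL36 (4.06), YUC10 (3.66), MYB3R2 (3.01), FWA (2.06) and IBM1 (2.04) were higher, although the imprinted genes lay at -0.38 and the methylation feedback genes at -0.92 relative to all features, and under TMM scaling both medians fell under 0 and the ratios of YUC10, MYB3R2, FWA and IBM1 under 1. Mature miRNAs that begin with A lay at -3.20 and those with U at -4.97 relative to all features, and 8 of the 13 with A and 66 of the 71 with U were at least 2-fold lower. Of those with A, miR408-5p was at 5.41, and miR840-5p (2.36) and miR390-5p (1.39) fell under 1 under TMM scaling.

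**Figure D5:**
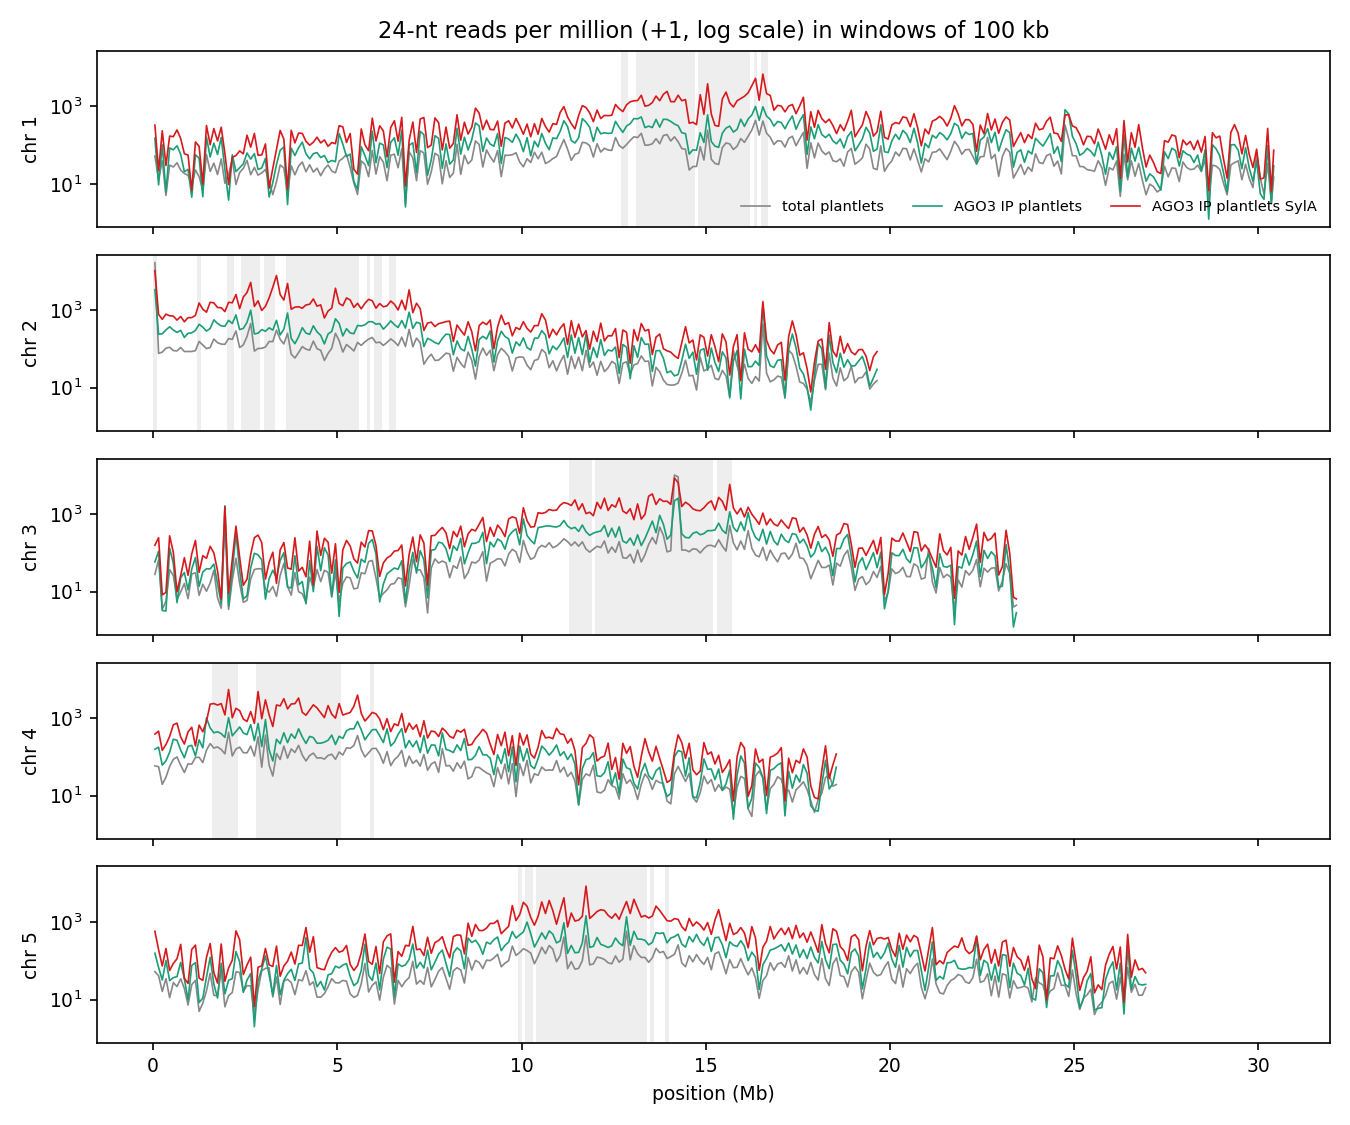
RPM of 24-nt reads plus 1 (vertical axis, log scale) in windows of 100 kb along chromosomes 1 to 5 (position in Mb, horizontal axis) for untreated total RNA, the untreated AGO3 IP and the SylA AGO3 IP of plantlets. Grey marks the 180 windows richer in pseudogene than in protein-coding bases, which hold 42.2% of single-match 24-nt reads of the SylA IP and 27.3% of the untreated IP. They hold 30.9% of those of untreated total RNA. With reads divided among all their matches, these shares are 48.5, 34.1 and 53.8%.

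In total RNA, SylA plantlets were compared with untreated ones to see how the treatment changed small RNAs before the IP. The 24-nt share rose by 4.80 points and the share with A in either orientation by 4.17 points. AGO3 rose from 13.2 to 43.3 RPM, a ratio of 3.28 (2.76 to 3.92), and AGO2 had a ratio of 1.65. MIR156h (AT5G55835, chromosome 5, 22597012 to 22597117) had the highest ratio at 26.0 (19.0 to 36.5), followed by TAT3 (AT2G24850, a tyrosine aminotransferase gene, 14.1), AT3G58270 (13.7), AT2G04460 (12.3) and AT1G58130 (5.70). GER3 (AT5G20630) was lowest at 0.0622 (0.0351 to 0.103), followed by PRK, FED A and SBPASE, which act in photosynthesis and carbon fixation, and PBP1, at 0.131 to 0.135. MIR168a (2.24) and MIR168b (2.08), whose miRNA targets AGO1, MIR163 (3.29), MIR396a (2.11) and AT4G03380 (3.91) had the most reads among higher features. Of 4382 features, 257 were higher, 128 lower and 91.2% within 2-fold, at a median log2 ratio of 0.53. TMM scaling moved log2 ratios by -0.53 and gave 35 higher and 298 lower features, and the denominator without structural and organellar RNA moved them by -0.45 and gave 41 and 262.

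The fixed lists stayed near all features in total RNA after SylA. Secondary siRNA protein genes lay 0.33 above (percentile 99.99), Argonaute genes (3 measured) 0.35, young miRNAs 0.12, TAS loci 0.08 and development miRNAs 0.04 above. Nutrient miRNAs lay at -0.26, imprinted genes and methylation feedback genes at -0.02. MIR166, MIR165, MIR159 and MIR157 had ratios of 1.09 to 1.43, MIR398, MIR408, MIR399 and MIR395 of 0.570 to 1.95, and MIR158, MIR161 and MIR173 of 1.42 to 1.797, and MIR166, MIR165, MIR159, MIR157, MIR398 and MIR158 fell under 1 under TMM scaling. TAS1C, TAS2, TAS3 and AT3G25795 had ratios of 0.976 to 1.61, AT1G62910, AT1G63130, AT1G63150 and AT1G63080 of 1.70 to 1.92, AGL36, MYB3R2 and FWA of 1.18 to 1.61, AT4G08680 of 1.28 and AGO1 of 1.85, and AGL36, MYB3R2 and AT4G08680 fell under 1 under TMM scaling. Among mature miRNAs, those with A as first base lay 0.35 above all features and those with U 0.02 above, so A lay above U before the IP as well. Reads at photosynthesis and proteasome genes were examined after the data were seen. Of 30 photosynthesis genes 29 were at least 2-fold lower, at -2.15 relative to all features, with RBCS1A (0.227), RBCS3B (0.304), RCA (0.202) and RBCS1B (0.223) holding the most reads. Of 27 proteasome subunit genes 3 were at least 2-fold higher, at 0.25 relative to all features, with RPT1A (1.97), RPT3 (1.66), RPN1A (1.68) and PAA2 (1.36, under 1 with TMM scaling) holding the most reads. In the other plantlet comparisons, photosynthesis genes lay at -3.97 in the untreated IP (29 genes) and at -6.71 in the SylA IP (6 genes) against total RNA, and at -5.06 in the SylA IP against the untreated IP (4 genes). Proteasome genes lay at -6.35 (10 genes) and -6.83 (20 genes) against total RNA, and with at least 20 reads 3 of 9 were higher and 2 lower in the SylA IP against the untreated IP.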

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

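No test in this part was chosen after the result was seen, and none of the differences below was tested, since each group held 1 library. Every library formed its own group, and none had others of its kind to be compared with.

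Several lists of small RNAs moved in opposite directions in 2 settings of the same comparison. The AGO3 IP over total RNA gave a median log2 ratio for development miRNAs of -0.71 in siliques and 1.805 in untreated plantlets. For young miRNAs these medians were -1.06 and 1.71, for TAS loci -1.09 and 1.67, and for secondary siRNA protein genes -0.94 and 1.49. Tissue and growth conditions differ together between siliques and plantlets. The IP over total RNA after SylA, against the untreated values, gave -1.13 and 1.805 for development miRNAs, -1.56 and 1.36 for nutrient miRNAs, -1.11 and 1.71 for young miRNAs, -1.18 and 1.67 for TAS loci and -1.01 and 1.49 for secondary siRNA protein genes. With structural and organellar RNA left out of the denominator, the untreated plantlet medians became 0.167 for development miRNAs, 0.0714 for young miRNAs and 0.0332 for TAS loci, and those of nutrient miRNAs (-0.27) and secondary siRNA protein genes (-0.15) lost their sign. SylA over untreated plantlets gave -1.904 in the IP and 0.65 in total RNA for young miRNAs, -2.44 and 0.61 for TAS loci and -1.600 and 0.87 for secondary siRNA protein genes. The median of all features in total RNA was 0.53. Relative to all features, these lists rose there by only 0.12, 0.08 and 0.33, and in the IP they lay at -3.87, -4.40 and -3.57.

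Some reads outside the comparisons were more frequent in an AGO3 IP than in its control library. Reads of 15 to 17 nt made up 23.01% of the silique AGO3 IP and 13.7% of the mock IP, and 19.5% of the untreated plantlet IP against 18.4% of total RNA, but 4.12% of the SylA IP against 22.6% of SylA total RNA. Reads of 16 nt alone made up 14.9% of the silique IP and 6.45% of the mock IP. Reads of 18 to 30 nt without an exact match to the genome made up 12.02% of those reads in the silique IP and 11.3% in the mock IP, 11.3% in the untreated plantlet IP and 8.11% in total RNA, and 13.1% in the SylA IP and 9.37% in SylA total RNA. No explanation was tested for these reads.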

How the results depend on the processing

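Tests chosen only after the results were seen were the sum over both listed orientations, the grouping of mature miRNAs by first base, the share of 24-nt reads in pseudogene-rich windows and the lists of photosynthesis and proteasome genes; the other alternatives were fixed before the data were examined. Values without the libraries or comparisons named follow a fixed order. The libraries run from the mock IP, the AGO3 IP and total RNA of siliques to untreated and SylA total RNA and then the untreated and SylA AGO3 IP of plantlets. The comparisons run from the silique IP over the mock IP, the silique IP over total RNA, the untreated plantlet IP over total RNA, the SylA IP over SylA total RNA and the SylA IP over the untreated IP to SylA total RNA over untreated total RNA. Each group held 1 library, so no paired analysis was possible and no library could be left out. List medians are on the log2 scale and share differences in percentage points. Where a value changed, the cause was not tested unless stated.

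With TMM scaling, the count of features at least 2-fold higher became 158 for the untreated plantlet IP over total RNA, 984 for the SylA IP over SylA total RNA, 1133 for the SylA IP over the untreated IP and 35 for SylA total RNA over untreated total RNA, and the count at least 2-fold lower became 1354 for the SylA IP over SylA total RNA, 1008 for the SylA IP over the untreated IP and 298 for SylA total RNA over untreated total RNA. 5 of the 12 counts stayed within 1.5 times their main value with TMM scaling. Under the same scaling, 29 of the 50 list medians kept their sign and their side of a 2-fold change. A median past 2-fold changed sign for imprinted genes from 2.11 to -0.38 for the SylA IP over SylA total RNA, imprinted genes from 1.59 to -0.36 for the SylA IP over the untreated IP, methylation feedback genes from 2.11 to -0.38 for the SylA IP over SylA total RNA, methylation feedback genes from 1.04 to -0.901 for the SylA IP over the untreated IP and Argonaute genes from 1.08 to -0.0292 for the untreated plantlet IP over total RNA. The development miRNAs moved to 0.700 for the untreated plantlet IP over total RNA. The nutrient miRNAs moved to 0.26 for the untreated plantlet IP over total RNA and past 0 from 0.27 to -0.26 for SylA total RNA over untreated total RNA. The young miRNAs moved to -0.88 for the silique IP over total RNA and 0.605 for the untreated plantlet IP over total RNA. The TAS loci moved to -0.91 for the silique IP over total RNA and 0.57 for the untreated plantlet IP over total RNA. The secondary siRNA protein genes moved to 0.39 for the untreated plantlet IP over total RNA. The imprinted genes moved to 0.304 for the untreated plantlet IP over total RNA, past 0 from -0.11 to 0.16 for the silique IP over the mock IP, past 0 from -0.15 to 0.0244 for the silique IP over total RNA and past 0 from 0.51 to -0.0185 for SylA total RNA over untreated total RNA. The methylation feedback genes moved to 0.24 for the untreated plantlet IP over total RNA, past 0 from -0.14 to 0.0344 for the silique IP over total RNA and past 0 from 0.52 to -0.0113 for SylA total RNA over untreated total RNA. The Argonaute genes moved to -3.45 for the SylA IP over SylA total RNA.

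With structural and organellar RNA left out of the denominator, the count of features at least 2-fold higher became 39 for the untreated plantlet IP over total RNA and 41 for SylA total RNA over untreated total RNA, and the count at least 2-fold lower became 1205 for the untreated plantlet IP over total RNA and 262 for SylA total RNA over untreated total RNA. 8 of the 12 counts stayed within 1.5 times their main value with structural and organellar RNA left out of the denominator. With that denominator, 35 of the 50 list medians kept their sign and their side of a 2-fold change. A median past 2-fold changed sign for nutrient miRNAs from 1.36 to -0.27 for the untreated plantlet IP over total RNA, secondary siRNA protein genes from 1.49 to -0.15 for the untreated plantlet IP over total RNA, imprinted genes from 1.41 to -0.23 for the untreated plantlet IP over total RNA, methylation feedback genes from 1.34 to -0.29 for the untreated plantlet IP over total RNA and Argonaute genes from 1.08 to -0.56 for the untreated plantlet IP over total RNA. The development miRNAs moved to 0.17 for the untreated plantlet IP over total RNA. The nutrient miRNAs moved past 0 from 0.27 to -0.18 for SylA total RNA over untreated total RNA. The young miRNAs moved to 0.0714 for the untreated plantlet IP over total RNA. The TAS loci moved to 0.0332 for the untreated plantlet IP over total RNA. The secondary siRNA protein genes moved to -1.09 for the silique IP over total RNA. The imprinted genes moved to 0.78 for the SylA IP over SylA total RNA. The methylation feedback genes moved to 0.78 for the SylA IP over SylA total RNA and 0.91 for the SylA IP over the untreated IP. The Argonaute genes moved to -1.05 for the silique IP over the mock IP and -2.29 for the SylA IP over SylA total RNA. Both scalings multiply every ratio of a comparison by 1 factor, which alone sets these changes.

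With structural and organellar reads left out of the shares, the difference in 24-nt share was -6.51, 5.1999, -3.35, 43.8, 51.7 and 4.505 in the order of the comparisons. In those reads, the difference in share of 24-nt reads with A in either orientation was 10.6, 14.4, 14.4, 20.1, 8.68 and 3.01 in the order of the comparisons. The 24-nt difference of the untreated plantlet IP over total RNA thereby turned from 9.28 to -3.35 points, since the reads left out made up 72.7% of total RNA and 14.99% of the IP.

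With only reads that match 1 position, the difference in 24-nt share was -7.85, 2.59, 11.004, 45.6, 41.98 and 7.42 in the order of the comparisons. Among these reads, the difference in share of 24-nt reads with A in either orientation was 11.02, 14.1, 14.7, 20.6, 9.03 and 3.06 in the order of the comparisons. With single-match reads, the count of features at least 2-fold higher became 584 for the silique IP over total RNA, 378 for the untreated plantlet IP over total RNA, 3537 for the SylA IP over SylA total RNA, 3427 for the SylA IP over the untreated IP and 93 for SylA total RNA over untreated total RNA, and the count at least 2-fold lower became 1309 for the silique IP over total RNA. 6 of the 12 counts stayed within 1.5 times their main value with single-match reads. For the lists with single-match reads, 30 of the 50 list medians kept their sign and their side of a 2-fold change. A median past 2-fold changed sign for methylation feedback genes from 1.34 to -0.15 for the untreated plantlet IP over total RNA and Argonaute genes from 1.08 to -0.31 for the untreated plantlet IP over total RNA. The development miRNAs moved to -1.56 for the silique IP over total RNA, 0.73 for the untreated plantlet IP over total RNA and past 0 from 0.402 to -0.0316 for the silique IP over the mock IP. The nutrient miRNAs moved to 0.56 for the untreated plantlet IP over total RNA. The pollen miRNAs moved to -1.03 for the silique IP over the mock IP. The TAS loci moved to 0.85 for the untreated plantlet IP over total RNA. The secondary siRNA protein genes moved to -1.38 for the silique IP over total RNA and 0.76 for the untreated plantlet IP over total RNA. The imprinted genes moved to 0.44 for the untreated plantlet IP over total RNA, 0.89 for the SylA IP over SylA total RNA and 0.89 for the SylA IP over the untreated IP. The methylation feedback genes moved to 0.88 for the SylA IP over SylA total RNA and 0.43 for the SylA IP over the untreated IP. The Argonaute genes moved to -1.09 for the silique IP over the mock IP, -1.14 for the SylA IP over SylA total RNA, -0.47 for the SylA IP over the untreated IP, 1.09 for SylA total RNA over untreated total RNA and past 0 from -0.24 to 0.55 for the silique IP over total RNA. Class shares of single-match reads, in the order of the libraries, were as follows. The miRNA share was 4.198, 4.78, 9.07, 16.6, 21.2, 41.8 and 4.64%. The TAS share was 0.509, 0.587, 1.48, 3.297, 4.27, 5.35 and 1.03%. The protein-coding share was 19.9, 22.9, 18.3, 16.2, 14.1, 6.61 and 10.7%. The pseudogene share was 8.18, 5.94, 7.74, 5.32, 6.64, 6.75 and 24.5%. The other ncRNA share was 5.89, 5.23, 5.33, 1.42, 1.45, 1.17 and 1.78%. The rRNA share was 1.69, 1.295, 1.99, 12.7, 8.01, 0.6404 and 0.1905%. The tRNA share was 0.0942, 0.0943, 0.214, 0.513, 0.388, 0.248 and 0.128%. The snRNA and snoRNA share was 3.71, 2.67, 0.442, 4.52, 2.6001, 1.23 and 0.136%. The chloroplast share was 3.19, 3.21, 2.95, 15.9, 10.5, 5.32 and 0.425%. The mitochondrion share was 0.9504, 0.516, 0.669, 2.86, 2.39, 0.723 and 1.32%. The unannotated share was 51.7, 52.8, 51.8, 20.7, 28.5, 30.1 and 55.1%. rRNA, chloroplast inverted-repeat and multi-copy tRNA reads drop out of this measure by its construction.

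With each distinct sequence counted once, the difference in 24-nt share was -7.42, 0.209, 24.9, 18.2, 0.625 and 7.29 in the order of the comparisons. Over distinct sequences, the difference in share of 24-nt reads with A in either orientation was 5.83, 12.4, 13.2, 21.4, 9.99 and 1.796 in the order of the comparisons. With distinct sequences, the count of features at least 2-fold higher became 142, 179, 48, 1676, 926 and 27 in the order of the comparisons, and the count at least 2-fold lower became 34 for the silique IP over the mock IP, 356 for the silique IP over total RNA, 322 for the untreated plantlet IP over total RNA, 358 for the SylA IP over SylA total RNA and 136 for the SylA IP over the untreated IP. 1 of the 12 counts stayed within 1.5 times their main value with distinct sequences. Among distinct sequences, class shares were as follows. Distinct miRNA sequences made up 0.267, 0.2402, 0.238, 0.337, 0.361, 0.525 and 0.2101%. Distinct TAS sequences made up 0.116, 0.119, 0.113, 0.203, 0.213, 0.378 and 0.0996%. Distinct protein-coding sequences made up 26.5, 24.1, 26.3, 32.6, 26.7, 12.9 and 12.1%. Distinct pseudogene sequences made up 15.7, 14.6, 18.1, 14.2, 16.9, 20.98 and 33.5%. Distinct other ncRNA sequences made up 2.73, 2.62, 2.13, 1.56, 1.64, 1.84 and 1.39%. Distinct rRNA sequences made up 3.88, 2.395, 1.54, 4.13, 3.89, 5.63 and 1.02%. Distinct tRNA sequences made up 0.322, 0.324, 0.258, 0.64001, 0.633, 0.3698 and 0.138%. Distinct snRNA and snoRNA sequences made up 1.08, 1.05, 0.323, 1.61, 1.17, 0.8004 and 0.147%. Distinct chloroplast sequences made up 4.03, 3.897, 3.03, 9.46, 5.93, 3.67 and 0.348%. Distinct mitochondrion sequences made up 1.74, 1.19, 1.27, 3.46, 3.28, 2.21 and 2.499%. Distinct unannotated sequences made up 43.6, 49.5, 46.7, 31.9, 39.2, 50.7 and 48.6%. Distinct 21-nt sequences with A at an end made up 51.2, 65.9, 55.2, 56.6, 58.4, 61.4 and 80.99%. Distinct 21-nt sequences with C at an end made up 36.9, 28.5, 33.5, 32.2, 29.9, 23.5 and 19.8%. Distinct 21-nt sequences with G at an end made up 41.5, 36.8, 40.8, 41.8, 41.5, 35.8 and 34.6%. Distinct 21-nt sequences with U at an end made up 46.4, 42.1, 44.7, 43.1, 43.5, 55.1 and 38.1%. Distinct 22-nt sequences with A at an end made up 52.95, 67.02, 54.5, 55.6, 57.6, 60.99 and 89.7%. Distinct 22-nt sequences with C at an end made up 37.3, 29.2, 35.7, 33.8, 31.8, 23.9 and 18.8%. Distinct 22-nt sequences with G at an end made up 41.7, 36.2, 40.3, 41.8, 41.9, 31.8 and 29.97%. Distinct 22-nt sequences with U at an end made up 44.3, 41.4, 44.2, 42.8, 42.6, 58.5 and 33.8%. Distinct 24-nt sequences with A at an end made up 73.5, 79.3, 66.9, 70.1, 71.9, 83.3 and 93.3%. Distinct 24-nt sequences with C at an end made up 23.4, 21.4, 29.1, 25.3, 24.2, 17.2 and 18.6%. Distinct 24-nt sequences with G at an end made up 38.8, 32.4, 37.7, 39.6, 38.5, 32.5 and 27.2%. Distinct 24-nt sequences with U at an end made up 34.9, 35.7, 38.2, 35.3, 35.1, 33.5 and 28.3%. The ends were read in either orientation.

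With reads of 20 to 25 nt as the whole, the difference in 24-nt share was -5.498, 4.76, 2.28, 51.4, 51.99 and 2.86 in the order of the comparisons. With both listed orientations summed, the difference in 24-nt share was -3.87, 5.98, 6.49, 55.9, 53.8 and 4.45 in the order of the comparisons. Without the 10 most abundant sequences of each library, the difference in 24-nt share was -4.67, 5.95, 30.8, 57.7, 32.5 and 5.62 in the order of the comparisons. After the same removal, the difference in share of 24-nt reads with A in either orientation was 9.54 for the silique IP over the mock IP, 28.8 for the SylA IP over SylA total RNA and 6.46 for SylA total RNA over untreated total RNA. Without these sequences, the count of features at least 2-fold higher became 3440 for the SylA IP over the untreated IP. 11 of the 12 counts stayed within 1.5 times their main value without these sequences. 12 of the 12 counts stayed within 1.5 times their main value with both orientations summed. With reads of 24 nt alone, the count of features at least 2-fold higher became 421 for the silique IP over the mock IP and 533 for the silique IP over total RNA, and the count at least 2-fold lower became 506 for the silique IP over total RNA, 191 for the untreated plantlet IP over total RNA, 186 for the SylA IP over SylA total RNA, 59 for the SylA IP over the untreated IP and 19 for SylA total RNA over untreated total RNA. 5 of the 12 counts stayed within 1.5 times their main value with reads of 24 nt alone.

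With a minimum of 20 reads, the count of features at least 2-fold higher became 2215 for the silique IP over the mock IP, 2769 for the silique IP over total RNA, 4807 for the untreated plantlet IP over total RNA and 1255 for SylA total RNA over untreated total RNA, and the count at least 2-fold lower became 4900, 2190, 3349, 3626, 1458 and 656 in the order of the comparisons. 2 of the 12 counts stayed within 1.5 times their main value with a minimum of 20 reads. With a minimum of 1000 reads, the count of features at least 2-fold higher became 252, 317, 320, 1915, 1972 and 20 in the order of the comparisons, and the count at least 2-fold lower became 102, 134, 108, 145, 107 and 9 in the order of the comparisons. A lower or higher minimum admits more or fewer features by its construction. For lists with a minimum of 20 reads, 48 of the 50 list medians kept their sign and their side of a 2-fold change. A median past 2-fold changed sign for Argonaute genes from -1.27 to 0.0102 for the SylA IP over the untreated IP. The Argonaute genes moved to -1.29 for the silique IP over the mock IP.

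Depth limits what a count of 0 can show: 3 counts correspond to 0.0719 RPM in total silique RNA and to 0.253 in SylA total RNA, the ends of the range over the 7 libraries.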

Other observations

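All tests in this part were chosen after the results were seen, except the test of A at the ends of mitochondrial reads.

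Small RNAs from 2 genes rose with SylA both in total RNA and in the IP of plantlets. NBR1 had 29.98 RPM in untreated total RNA and 52.2 RPM after SylA, and 0.413 and 31.3 RPM in the IP. TAT3 had 6.88 and 97.4 RPM in total RNA and 2.83 and 70.8 RPM in the IP. Of the NBR1 reads of the SylA IP, 6.26% were 24 nt and 18.1% were 21 nt long. TAT3 reads were 77.3% 21 nt and 9.70% 24 nt in SylA total RNA. In the SylA IP they were 29.2% 21 nt and 62.5% 24 nt. Reads of 20 to 22 nt at MIR genes began with A in 6.54% of the SylA IP and in 0.312 to 1.68% of the other libraries. All such reads were taken as sense. They numbered 9.08e+06 in the untreated plantlet IP and 1.06e+06 in the SylA IP. U began 98.9% and 92.7% of them, so the A share also moves with the number of reads that begin with U.

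The AGO3 IP of plantlets held 46.4% reads of 21 nt when untreated and 74.8% reads of 24 nt after SylA, a rise of the 24-nt share by 52.3 points. Without the 10 most abundant sequences of each library the rise was 32.5 points, which argues against a few abundant sequences as the whole cause, although it was 0.625 points among distinct sequences. The 24-nt share of total RNA rose by 4.80 points, under the rise in the IP, and the miRNA share of the untreated IP was 54.8%, above both total RNA (9.50%) and the SylA IP (6.46%), which argues against total RNA carried into the untreated IP. A change in what AGO3 holds after SylA may underlie the rise, as a hypothesis found and tested on the same libraries. RNA held by the gel without AGO3 cannot be weighed, since no mock IP of plantlets was among the libraries. The AGO3 locus had 13.9 RPM in the untreated IP and 13.2 in its total RNA. U stood at an end, in either orientation, of 95.9% of 21-nt reads of the untreated IP. This share was 69.0% in untreated total RNA and 82.1% in the SylA IP. A single MIR166a sequence held 4608887 of the 7872700 21-nt reads of the untreated IP. Among distinct 21-nt sequences the share with U was 55.1% in the untreated IP, 43.1% in untreated total RNA and 38.1% in the SylA IP. A difference between the 2 IP preparations stays open, since each is 1 library and no level of AGO3 protein is among the data.

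Most features of the silique AGO3 IP lay near the mock IP, with 73.5% of them within 2-fold. Reads of the AGO3 locus were higher in the library labelled AGO3 IP by a ratio of 10.1, which argues against swapped labels, and 105 of 3624 features with at least 5 RPM in the AGO3 IP had a ratio of mock IP to AGO3 IP wholly under 0.1, which argues against carry-over of the AGO3 IP library. The share of snRNA and snoRNA was 8.12 times as high in the mock IP as in total RNA of siliques, but in plantlets it was lower in the IP (0.577% untreated, 0.235% after SylA) than in total RNA (1.35% and 0.918%), so RNA of this class brought in by the IP procedure cannot be told apart from a low share in the total silique library. For all features, RNA held by the gel cannot be told apart from RNA common to the tissue, because 78.0% of them lay within 2-fold of total RNA as well. A weak enrichment by the tagged protein in siliques may be part of the likeness and was not tested.

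Reads of 24 nt that match the mitochondrial genome rose from 2863 RPM in the untreated plantlet IP to 34125 RPM in the SylA IP, and from 1.14 to 4.12% of all 24-nt reads. In the SylA IP 81.1% of them also matched a nuclear chromosome, against 46.8 to 73.1% in the other libraries, and since reads of mitochondrial origin match the nuclear copies of the reference too, the 2 origins cannot be told apart for these reads. Reads that match the mitochondrial genome only rose from 636 to 6407 RPM. Their ends had A in either orientation 52.5 points more often than inner positions, against 29.7 points in the untreated IP and 13.2 to 23.3 points in the other libraries, which argues against fragments of mitochondrial RNA without an Argonaute. Nuclear copies missing from the reference may account for them and were not tested.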
